A study of Mus musculus with 2 samples.

How the data were processed

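The 2 libraries hold 10x Genomics 3' single-cell RNA counts of mouse hippocampal cells, each from a pool of 3 mice. The deposited matrices hold raw UMI counts per gene and cell barcode, as whole numbers, for 41605 genes. Per the file headers and the submitters' notes they were made with Cell Ranger 3.0.1, on genome build GRCm38.p5. No normalization had been applied. No barcode in either library had fewer than 500 UMIs, and the step that set this limit is not given in the sources used here. The series describes 2 ways of dissociation but no label ties a library to either, so no group was assigned, and none was inferred from the counts. The sample number in the files of library 2 differs from that in its title, which the sources do not explain.

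The settings in this paragraph, the gene groups, the cell type markers, the rule for named genes and the alternatives were fixed before the data were examined. Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrially encoded UMIs. In library 1, 7664 barcodes passed the first limit, 7627 the first and second and 7209 all 3, so the mitochondrial limit removed 418. In library 2 these numbers were 4078, 3570, 2164 and 1406. Doublets were scored per library with Scrublet in scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes. The automatic threshold marked 12.8% of the barcodes of library 1. It marked 0.0775% of library 2, under the accepted minimum of 0.5%, so the expected share of barcodes with the highest scores (5.16%) was taken there. This removed 1220 further cells of library 1 and 89 of library 2. Both libraries were clustered together without batch correction. Counts were scaled to 10000 UMIs and logged, and a single set of 2000 variable genes was chosen from rankings made within each library. Clustering used 30 principal components, 15 neighbours and Leiden resolution 1 with leidenalg 0.10.2 and seed 0. The immediate early, heat shock, NF-kB, interferon and unfolded protein response genes were kept out of the variable genes, as were mitochondrially encoded, ribosomal protein and haemoglobin genes, so that their level did not decide which cells form a class.

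Clusters were named from 18 marker lists, and the thresholds for this were set after the clusters had been seen. A marker counted as raised at 2 or more times its mean over clusters (with 10 CPM added) and at least 20 CPM, and a class needed 3 raised markers. A cluster in which a second class reached 0.5 of the best score with 0.5 of its markers raised, or had 0.75 of its markers raised with a mean fold of at least 2, was clustered once more with 10 components. It stayed unnamed if still mixed. Clusters under 20 cells, clusters with more markers of another class among their 10 leading genes, sub-clusters with no marker of their own among these, and clusters with a median below 0.333 of the library's UMIs and no such marker also stayed unnamed. The 28 clusters gave 45 clusters and sub-clusters, of which 18 were unnamed. Names carry the ending "-like", since they rest on RNA markers alone. The 18 unnamed ones include a haemoglobin-led group that also held the microglia markers, and all border-associated macrophage, monocyte and neutrophil clusters, each of which had fewer than 20 cells.

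UMIs were summed over the cells of each class and library and divided by that class's total (CPM), since cells are not replicates. Intervals are exact at the 95% level (Poisson for counts, Clopper-Pearson for shares) with scipy 1.17.1. A count of 0 is read as allowing 3 counts. PCR copies are removed by the UMIs, but intervals cover counting error only, not differences between animals or preparations. Classes with at least 50 cells in a library were compared with the microglia-like cells of that library. The ratio per gene was log2 of the CPM plus 1 in microglia-like cells over the CPM plus 1 in the mean of the other classes. The median over each of 13 gene groups was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Intervals of these medians come from 1000 Poisson redraws of the counts. For shares of cells with a UMI, each cell was thinned to 1000 UMIs, and 0 cells of the classes compared had fewer. No test with replicates was possible between the libraries, because each is a single pool. The closing section gives ratios of the unassigned libraries with counting intervals, list percentiles and a ratio at like depth, with no method attached.

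In the report the named genes of a group are the up to 6 with the highest CPM in the class described, averaged over both libraries, plus any with a microglia-like CPM at least 4 times that of every other class with at least 50 cells in both. In the closing section they are the 12 genes with the highest and the 12 with the lowest ratio of the 2 libraries in microglia-like cells, ranked by the interval bound nearest to 1, among 3768 genes with at least 100 UMIs, at least 50 CPM in 1 library and no role as a marker of another class. No other class had 200 cells in both libraries. Some genes that the rule names are not reported here. Fos and Egr1 in the shares of cells with a UMI, and the neuronal, astrocytic and vascular markers named as such, were chosen outside this rule. Gene coordinates are those of the GENCODE annotation of GRCm38, in which all 293 listed genes were matched by identifier.

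The ratio of 2 pooled counts and the list percentile were tested on simulated data with the depths of the microglia-like cells. Both simulated libraries were drawn from 1 shared profile with Poisson counting error only, as the intervals assume. The test therefore checks the calculation and says nothing on differences between cells, clusters, animals or preparations. Among 8817 simulated genes the interval excluded 1 for 94% of genes raised 2 times, 82% of genes lowered to 0.5, 100% of genes raised 4 times and 98% of genes lowered to 0.25. For unchanged genes it was set against their own median ratio (0.996), which it excluded for 4.54%. A simulated list of 27 genes raised 2 times lay at percentile 100, and 4 of 100 unchanged lists lay outside the central 95%.

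The alternatives tried were at least 500 UMIs and 250 genes, at least 2000 UMIs, at most 20% mitochondrial UMIs, no doublets removed, Leiden resolutions of 0.5 and 2, response genes allowed in the clustering, each library clustered on its own, CPM over nuclear-encoded genes only, 10 CPM added in place of 1, and only genes with at least 20 UMIs. They were planned for 10 results and applied to 68 others after the data had been seen. Where a setting changed which classes had at least 50 cells, the medians were also taken against the classes of the reported comparison, whatever their number of cells, which was added after the data had been seen. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.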

Results

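Droplet-based single-cell RNA sequencing (10x Genomics 3' chemistry, version 3) was run on 2 libraries of hippocampal cells from wild-type C57BL/6 male mice 10 weeks of age. Each library held the pooled cells of 3 mice. The series sets cells released by enzymes for 30 min at 37 °C against cells released mechanically at 4 °C, to ask how digestion shifts the RNA of brain cell populations. The labels do not say which library had which treatment, so both libraries are unassigned here, are called library 1 and library 2, and cannot stand for a method. The files of library 2 also carry another sample number than its title, and the sources used here do not say why. Comparisons in the report are therefore between cell classes of 1 library, with the values of the other library beside it. Ratios between the libraries are given only in the closing section, as values of unassigned samples. There are no replicates, so the 95% intervals cover counting error only, not differences between libraries or animals.

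Library 1 held 12306 cell barcodes with 18783691 unique molecular identifiers (UMIs) in all, a median of 1256 UMIs per barcode and a median mitochondrially encoded share of 1.76%. Library 2 held 6448 barcodes with 29356086 UMIs, a median of 1600.5 UMIs and a median mitochondrial share of 13.3%. After the filters on depth, mitochondrial share and doublets, 5989 cells of library 1 (48.7% of its barcodes, median 1695 UMIs) and 2075 cells of library 2 (32.2%, median 6433 UMIs) were kept. Levels are given as counts per 1000000 UMIs of a class (CPM), from the UMIs of a gene or gene group summed over all cells of that class in 1 library.

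The first question was which cell classes each library held. Library 1 was mostly neuron-like, with 4618 cells or 77.1% of those kept (exact binomial 95% interval 76.0 to 78.2%). Microglia-like cells, the resident macrophages of the brain by their markers, were 663 cells of library 1 (11.1%, 10.3 to 11.9%) and 1448 cells of library 2 (69.8%, 67.8 to 71.8%). Library 1 also held 301 astrocyte-like cells (5.03%, 4.49 to 5.61%) and 109 oligodendrocyte-like cells (1.82%, 1.497 to 2.19%). Library 2 held 191 endothelial-like cells (9.20%, 7.995 to 10.5%), 83 pericyte-like or smooth muscle-like cells (4.00%, 3.20 to 4.93%) and 50 oligodendrocyte-like cells (2.41%, 1.79 to 3.16%). Only 37 cells of library 2 were neuron-like (1.78%, 1.26 to 2.45%), 23 were astrocyte-like (1.11%), and only 5 cells of library 1 were endothelial-like (0.0835%) and 1 was pericyte-like (0.0167%). Choroid plexus-like cells numbered 41 in library 1 and 8 in library 2, fibroblast-like cells 40 and 36, and T or NK-like cells 5 and 18. The choroid plexus-like numbers rested on the mitochondrial limit: at 20% they were 103 in library 1 and 138 in library 2. Library 2 then also held 57 border-associated macrophage-like cells. Clusters with no clear class held 206 cells of library 1 (3.44%) and 181 cells of library 2 (8.72%). The shares of library 1 rested on the depth filter: with at least 2000 UMIs its microglia-like share was 19.7% and its astrocyte-like share 0.999%, and with at least 500 UMIs and 250 genes its astrocyte-like share was 13.8% and its oligodendrocyte-like share 12.7%. The oligodendrocyte-like share was 1.11% in library 1 with no doublets removed and 1.59% in library 2 clustered on its own. The endothelial-like share of library 2 ran from 6.14 to 9.65% across the alternatives. Neuron-like cells of library 2 numbered 195 of 2377 with at least 500 UMIs and 250 genes, 58 of 2829 with a mitochondrial limit of 20% and 0 of 2075 when it was clustered on its own.

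**Figure D1:**
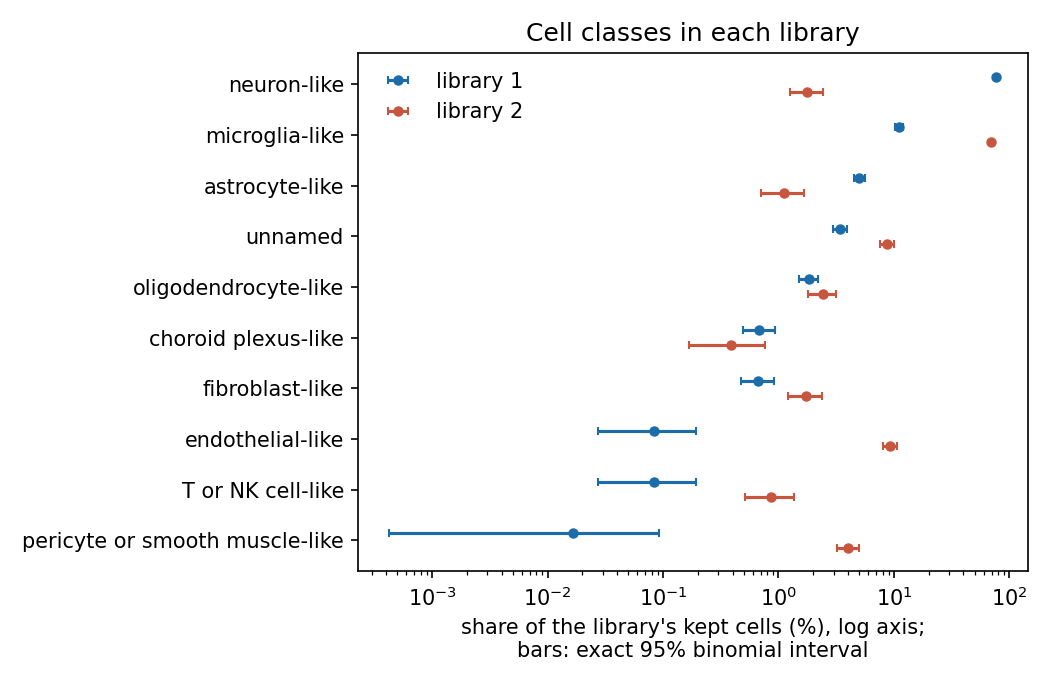
Share of kept cells in each class (%, log axis) for library 1 and library 2, with exact 95% binomial intervals as bars. Neuron-like cells made up 77.1% of library 1 and microglia-like cells 69.8% of library 2.

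Microglia-like cells were then set against the other classes with at least 50 cells of the same library: neuron-like, astrocyte-like and oligodendrocyte-like cells in library 1, and endothelial-like, pericyte-like and oligodendrocyte-like cells in library 2. The homeostatic microglia genes, which mark resting microglia, were the most class-restricted group. All 12 had a microglia-like level at least 4 times that of every other class in both libraries, and together they made up 35028 CPM (34728 to 35330) in library 1 and 34054 CPM (33940 to 34170) in library 2. P2ry12, a purinergic receptor of resting microglia (ENSMUSG00000036353, GRCm38 chromosome 3, 59216272 to 59262871), reached 3748 and 3175 CPM, and the fractalkine receptor Cx3cr1 3189 and 4742 CPM. Csf1r, the receptor for the microglial survival factor CSF1, stood at 3298 and 3556 CPM, Selplg at 3201 and 3308 CPM, and Gpr34 at 2106 and 2366 CPM. Tmem119, Olfml3, Fcrls, Siglech, P2ry13 and the transcription factor gene Sall1 ranged from 301.6 CPM (Sall1) to 2039 CPM (Olfml3) in library 1 and from 330.5 CPM (Sall1) to 1738 CPM (Tmem119) in library 2. The median log2 ratio over the mean of the other classes was 7.24 (7.02 to 7.49) in library 1 and 6.32 (6.22 to 6.64) in library 2, above all of 10000 random gene lists matched on expression. Some alternative settings change which classes reach 50 cells, and the value against the same 3 classes is then given as well. The median was 3.10 in library 2 with at least 2000 UMIs, where 50 erythrocyte-like cells joined the comparison and oligodendrocyte-like cells left it, and 6.49 against the same 3 classes. It was 5.93 in library 1 with no doublets removed, where fibroblast-like cells joined, and 6.96 against the same 3 classes. In library 2 with no doublets removed it was 5.13, with the same 3 classes compared.

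Genes of the disease-associated microglia programme, a lysosomal and lipid-handling state, summed to 18145 CPM (17929 to 18363) in microglia-like cells of library 1 and 17056 CPM (16975 to 17138) in those of library 2. Most of this came from genes that resting microglia also express. The lysosomal protease gene Ctsd (ENSMUSG00000007891, chromosome 7, 142375911 to 142388038) stood at 7562 CPM and 7127 CPM, the signalling receptor Trem2 at 2805 and 2324 CPM, its adaptor Tyrobp at 2701.5 and 2479 CPM, Ctsb at 1604 and 1377 CPM, and Cd9 at 1123 and 967 CPM. Apoe, which carries lipids between cells, was higher in astrocyte-like cells of library 1 (14790 CPM, 14419 to 15167) than in microglia-like cells (1210.4 CPM there and 1004 CPM in library 2). Cst7, a cysteine protease inhibitor typical of the activated state (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944), reached only 6.73 CPM (3.23 to 12.4) and 14.5 CPM (12.2 to 17.0). In library 1, 12 of 16 genes were higher in microglia-like cells than in the mean of the other classes (median log2 ratio 2.33, 1.77 to 2.46, percentile 100), and in library 2 it was 11 of 16 (1.4999, 1.08 to 1.57, percentile 99.96). With 10 CPM added in place of 1 the medians were 0.75 and 0.64, and with at least 2000 UMIs that of library 2 was 0.23 (1.37 against the same 3 classes).

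The immediate early genes, transcribed within minutes of a stimulus, bear on the series' question of what digestion at 37 °C does to cells. In microglia-like cells they summed to 2508 CPM (2428 to 2589) in library 1 and 21176 CPM (21086 to 21267) in library 2. In library 1 the oligodendrocyte-like cells stood at 1408 CPM (1272 to 1555), the neuron-like cells at 846 CPM (826 to 865) and the astrocyte-like cells at 479.9 CPM (415.1 to 552.0). In library 2 the endothelial-like cells came close to the microglia-like cells with 18549 CPM (18397 to 18702), while oligodendrocyte-like cells had 2299.7 CPM (2168 to 2437) and pericyte-like cells 1815 CPM (1681 to 1956). Of the 191 endothelial-like cells, 41 lay in a cluster with a median of 36509 UMIs. The clusters that held 101 and 49 of them had medians of 5005 and 8741 UMIs. Summed levels of this class, here and below, thus give these 41 cells more weight, and its clusters were not compared.

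Of the single genes, Jun, a subunit of the AP-1 transcription factor (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222), reached 3509.99 CPM (3473 to 3547) in microglia-like cells of library 2 and 142 CPM (124 to 163) in those of library 1. Its relative Junb (ENSMUSG00000052837, chromosome 8, 84974484 to 84978718) stood at 2839.8 and 306 CPM, and Jund at 1932 and 221 CPM, in the same order. Zfp36, which speeds the decay of cytokine mRNAs, was at 1878 CPM (1851 to 1905) and 41.7 CPM (32.0 to 53.5), and the anti-proliferative gene Btg2 at 1524 and 248 CPM. Rhob, a small GTPase gene induced by stress, led the group in microglia-like cells of library 1 with 1025 CPM (974 to 1077) and stood at 2053 CPM in library 2. Endothelial-like cells of library 2 held much of the same group, with Jun at 2518 CPM, Junb at 1723 CPM, Fos at 1637 CPM and Jund at 1465 CPM, but their leading member was Klf2, the shear-stress transcription factor gene of endothelium, at 2964 CPM (2903 to 3026) against 307 CPM in microglia-like cells. Neuron-like cells of library 1 held few transcripts of this group, with Junb at 99.6 CPM, Btg2 at 90.2 CPM and Jun at 78.1 CPM.

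No immediate early gene had a microglia-like level at least 4 times that of every other class in both libraries. In library 2, 19 of 27 genes were above the mean of the other classes (median log2 ratio 1.17, 1.11 to 1.23, percentile 99.98), with a median of 3.48 over oligodendrocyte-like, 3.31 over pericyte-like and -0.02 over endothelial-like cells. The median of library 2 was 0.59 with the library clustered on its own, where oligodendrocyte-like cells left the comparison, and 2.04 with a mitochondrial limit of 20%, where 4 classes joined it. Against the same 3 classes these were 1.03 and 1.23. In library 1, 15 of 27 were above that mean and 12 below (median 0.44, percentile 99.1), an interval of -0.17 to 0.64 that spans 0. That median turned to -0.12 with at least 500 UMIs and 250 genes, where 4 classes joined, and was 0.67 against the same 3 classes. As its interval spans 0, the direction of this median over the mean was not detectable in library 1 at this depth. Over the single classes of library 1 the medians were 1.45 (astrocyte-like, 20 of 27 genes higher), 0.78 (neuron-like, 14 of 27) and 0.80 (oligodendrocyte-like, 18 of 26). The summed level was also above that of each of these classes. With at least 500 UMIs and 250 genes the oligodendrocyte-like level of library 1 was 772 CPM. With at least 2000 UMIs the astrocyte-like level was 771 CPM in the 21 cells left, below the 50 cells asked of a class.

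**Figure D2:**
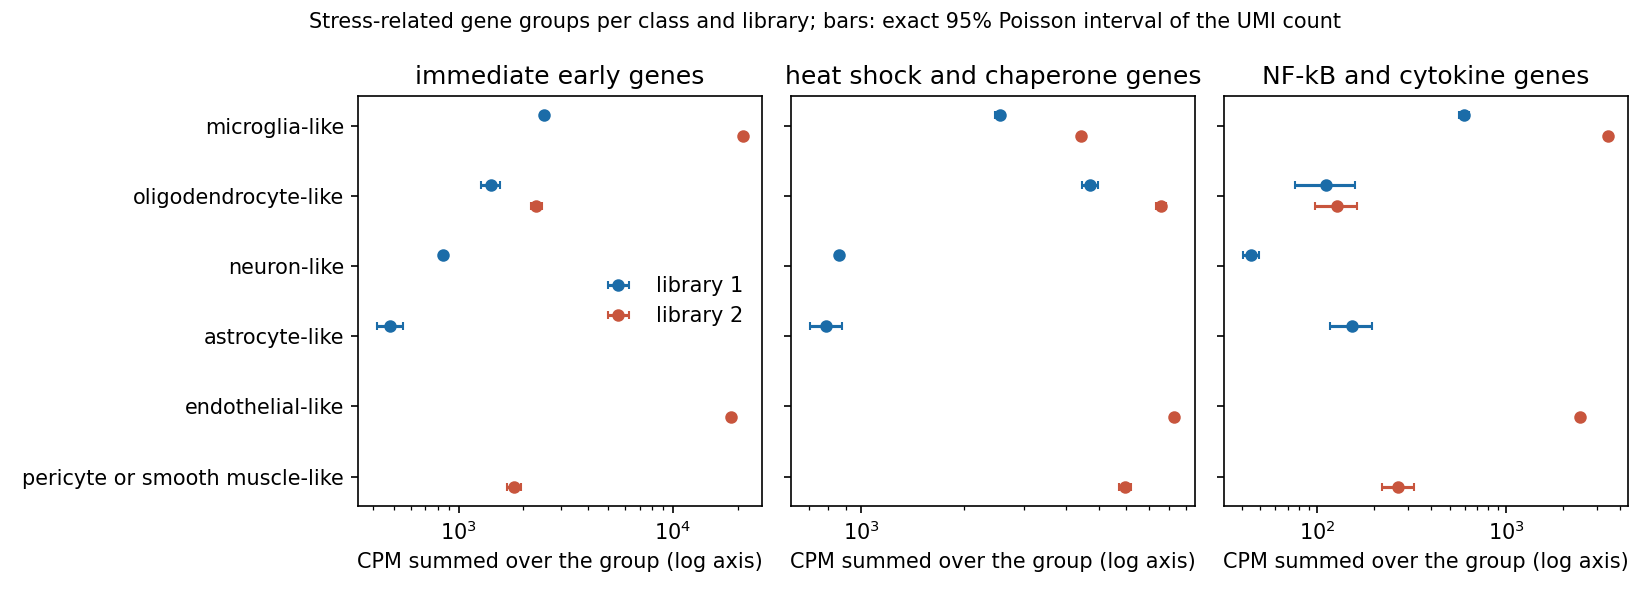
Summed level (CPM, log axis) of the immediate early, heat shock and NF-kB groups in each class with at least 50 cells, library 1 and library 2, with exact 95% Poisson intervals as bars. Immediate early genes reached 21176 CPM in microglia-like and 18549 CPM in endothelial-like cells of library 2, against 2508 CPM in microglia-like cells of library 1.

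Heat shock and chaperone genes, which keep proteins folded, were not led by microglia-like cells. Their sum was 2549 CPM (2469 to 2632) in microglia-like cells of library 1, below the 4699.8 CPM (4448 to 4962) of oligodendrocyte-like cells and above the 788 CPM (705 to 879) of astrocyte-like and the 861 CPM (841 to 880.3) of neuron-like cells. In library 2 it was 4418 CPM (4377 to 4459.8) in microglia-like cells, the lowest of the 4 classes compared, against 8314 CPM (8212 to 8417) in endothelial-like, 7594 CPM (7354 to 7839.96) in oligodendrocyte-like and 5966 CPM (5721 to 6218) in pericyte-like cells. The constitutive chaperone genes Hspa8 and Hsp90ab1 made up most of the microglia-like sum, with 924 CPM (876 to 974.5) and 825 CPM (779 to 872) in library 1 and 1382.5 and 1112 CPM in library 2. Dnaja1, a co-chaperone gene, stood at 263 and 339.9 CPM, Hsp90aa1 at 195 and 361 CPM, and the mitochondrial co-chaperone gene Hspe1 at 165 and 203 CPM. Hspa1b, a stress-induced member (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), was at 3.37 CPM (1.09 to 7.85) in library 1 and 388 CPM (376 to 400.4) in library 2. Its near-identical neighbour Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) can share reads with it, so the 2 are not told apart with certainty. In endothelial-like cells Hspa1a stood at 626 CPM, Hspa1b at 515 CPM and the small heat shock gene Hspb1 at 1495 CPM (1452 to 1539), and oligodendrocyte-like cells held most Hsp90aa1, with 1102 CPM in library 1 and 2129 CPM in library 2.

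Over the mean of the other classes, 8 of 12 heat shock genes were higher in microglia-like cells of library 1 (median log2 ratio 0.50, 0.16 to 0.66, percentile 90.1) and 4 of 12 in library 2 (median -0.64, -0.76 to -0.42, percentile 7.0). Neither median lay outside the central 95% of the random lists. With at least 2000 UMIs the median of library 1 was 1.30, against neuron-like cells only, since 21 astrocyte-like (1261 CPM) and 35 oligodendrocyte-like cells were left, and 0.16 against the same 3 classes. With at least 500 UMIs and 250 genes its oligodendrocyte-like level was 2595 CPM.

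NF-kB and cytokine genes, which carry inflammatory signals, were the only response group whose median ratio lay above all random lists in both libraries. By summed level, immediate early and unfolded protein response genes were also highest in microglia-like cells among the classes compared in both libraries. For immediate early genes of library 2 this order was narrow. Across the alternatives their level ran from 20875 to 22105 CPM in microglia-like and from 17657 to 21209.5 CPM in endothelial-like cells, so the ranges overlap. NF-kB and cytokine genes summed to 596 CPM (558 to 637) in microglia-like cells of library 1, against 152 CPM (116 to 195) in astrocyte-like, 112 CPM (75.9 to 158) in oligodendrocyte-like and 44.7 CPM (40.3 to 49.3) in neuron-like cells. In library 2 they summed to 3454 CPM (3417 to 3490.5) in microglia-like cells, against 2456 CPM (2401 to 2512) in endothelial-like, 268 CPM (219 to 326) in pericyte-like and 127 CPM (97.2 to 162) in oligodendrocyte-like cells. Ccl4, a chemokine gene (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683), stood at 43.1 CPM (33.2 to 55.0) in microglia-like cells of library 1 and 1025 CPM (1005 to 1045) in those of library 2. In library 1 the level of Ccl4 rests on few cells, as only 1.36% of the 663 held a UMI of it. Its neighbour Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) stood at 46.4 CPM (36.1 to 58.8) and 558 CPM (543 to 572). Endothelial-like cells drew their sum from other members, with Nfkbia, the feedback inhibitor of NF-kB, at 1375 CPM, the prostaglandin synthase gene Ptgs2 at 453 CPM (429.9 to 478) and the adhesion molecule gene Icam1 at 325 CPM. In microglia-like cells Nfkbia stood at 118 and 693 CPM and Icam1 at 129 and 241 CPM.

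In both libraries 9 of the 20 genes had a microglia-like level at least 4 times that of every other class compared: Ccl2, Ccl3, Ccl4, Ccl12, Tnf, Il1a, Cd83, Tnfaip3 and Bcl2a1d. Cd83, a surface protein of activated immune cells, stood at 56.5 and 139 CPM, the interleukin gene Il1a at 59.2 and 132 CPM, Ccl12 at 58.6 and 106 CPM, and the NF-kB inhibitor gene Tnfaip3 at 18.8 and 105 CPM. Ccl2 had 12.8 and 40.9 CPM, Tnf 4.04 CPM (1.48 to 8.79) and 73.0 CPM, and Bcl2a1d, whose reads can be shared with its paralogs, 2.69 CPM (0.734 to 6.89) and 4.65 CPM (3.40 to 6.20). In oligodendrocyte-like cells of library 1 a count of 0 allows up to 10.8 CPM. Ccl4 stood at 3.99, Tnfaip3 at 1.74 and Ccl2 at 1.18 times this limit, and Tnf and Bcl2a1d below it, so for these 5 genes the restriction was not detectable at the depth of that library. For Bcl2a1d this held in library 2 as well, where pericyte-like cells allow up to 7.97 CPM. The median log2 ratio over the mean of the other classes was 2.58 (2.01 to 3.00, 16 of 20 genes higher) in library 1 and 2.55 (2.32 to 3.13, 18 of 20) in library 2, both above all random lists. With 10 CPM added in place of 1 they were 0.74 and 1.58, over genes with at least 20 UMIs that of library 1 was 3.79, and with at least 2000 UMIs that of library 2 was 1.95 (2.56 against the same 3 classes) and the pericyte-like level 411 CPM.

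**Figure D3:**
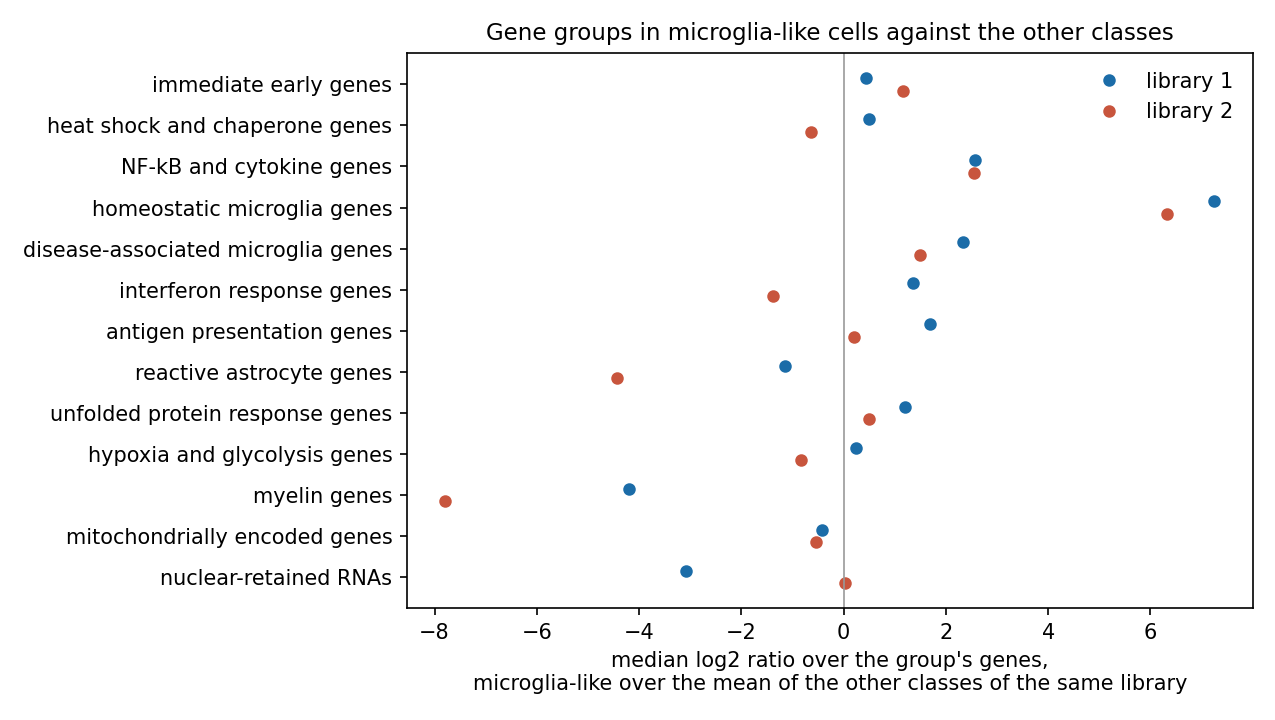
Median log2 ratio of each gene group, microglia-like cells over the mean of the 3 other classes of the same library, for library 1 and library 2. Homeostatic microglia genes stand at 7.24 and 6.32, NF-kB and cytokine genes at 2.58 and 2.55, and immediate early genes at 0.44 and 1.17.

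Interferon response genes were low in microglia-like cells, with 246 CPM (222 to 273) in library 1 and 271 CPM (261 to 282) in library 2, led by the antiviral membrane protein gene Bst2 at 109.7 and 134 CPM. Library 2 held more of them in endothelial-like cells (2548 CPM, 2492 to 2606) and pericyte-like cells (1020.4 CPM, 921 to 1128), where Ifitm3, which blocks viral entry, stood at 1871 CPM and 848 CPM. The microglia-like median was 1.36 (0.95 to 2.01, 11 of 12 genes higher, percentile 99.9) in library 1, where the other classes held 83.3 CPM (astrocyte-like), 57.6 CPM (oligodendrocyte-like) and 26.8 CPM (neuron-like). It was -1.37 (-1.68 to -1.14, 10 of 12 lower, percentile 1.62) in library 2. The classes compared differ between the libraries, so the opposite signs do not compare the microglia-like cells of the libraries. With at least 500 UMIs and 250 genes the median of library 1 was 0.49 (1.41 against the same 3 classes), and with at least 2000 UMIs 2.53 (2.29).

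Antigen presentation genes summed to 1344 CPM (1286 to 1405) in microglia-like cells of library 1 and 2227 CPM (2197 to 2256) in those of library 2, most of it from class I genes: B2m, the light chain, at 615 and 1303 CPM, H2-D1 at 237 and 369.6 CPM and H2-K1 at 277 and 314.5 CPM. Endothelial-like cells of library 2 stood higher, at 3361 CPM (3296 to 3427), with H2-D1 at 1177 CPM. The class II chaperone gene Cd74 stood at only 14.8 and 34.5 CPM in microglia-like cells. The median log2 ratio was 1.68 (1.21 to 2.42, 7 of 10 genes higher, percentile 99.9) in library 1 and 0.21 (-0.14 to 0.46, 5 of 9 higher, percentile 81.1) in library 2. The second turned to -0.0341 with at least 2000 UMIs, -0.89 with a mitochondrial limit of 20% and -0.47 when the library was clustered on its own. Against the same 3 classes these were 0.24, 0.26 and 0.08.

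Unfolded protein response genes, which serve folding in the endoplasmic reticulum, stood at 2401 CPM (2322 to 2481) and 2528 CPM (2497 to 2559.7) in microglia-like cells, led by the chaperone genes Hsp90b1 (776 and 908 CPM) and Hspa5 (650.3 and 673 CPM). Other classes of library 1 stood at 1152 CPM (oligodendrocyte-like), 793 CPM (astrocyte-like) and 711 CPM (neuron-like). Those of library 2 stood at 1780 CPM (pericyte-like), 1493 CPM (endothelial-like) and 1340 CPM (oligodendrocyte-like). The microglia-like level was above the mean of the other classes for 10 of 11 genes in library 1 (median 1.20, 0.97 to 1.40, percentile 98.2) and 9 of 11 in library 2 (0.49, 0.34 to 0.69, percentile 94.2). Hypoxia and glycolysis genes stood at 776 CPM (732 to 822) and 1150.4 CPM (1129 to 1172), with medians of 0.24 (-0.09 to 0.41, percentile 77.3) and -0.83 (-0.95 to -0.68, percentile 4.5). Hk2, a hexokinase of glycolysis, was the 1 member with at least 4 times the level of every other class in both libraries, at 120.5 CPM (103 to 139.5) and 478 CPM (464 to 491). Endothelial-like cells of library 2 led this group with 4901 CPM, of which the glucose transporter gene Slc2a1 took 2868 CPM. Reactive astrocyte genes were low in microglia-like cells, at 15.5 CPM (9.82 to 23.2) and 11.9 CPM (9.87 to 14.3), with medians of -1.14 (percentile 25.2) and -4.44 (percentile 0.0). In astrocyte-like cells of library 1 they summed to 426 CPM (365 to 494), of which the intermediate filament gene Gfap took 353 CPM (297 to 415), and in endothelial-like cells of library 2 to 2320.4 CPM, of which Vim took 1180.5 CPM and Lcn2 634 CPM. With at least 2000 UMIs the medians of library 1, then against neuron-like cells only, were 1.06 for hypoxia and glycolysis and -0.24 for reactive astrocyte genes, and -0.44 and -2.40 against the same 3 classes. Over the alternatives the reactive astrocyte median of library 2 ran from -6.07 to -1.78.

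Nuclear-retained RNAs, long non-coding transcripts that stay in the nucleus, made up a large part of the neuron-like and astrocyte-like profiles of library 1. They took 207228 CPM (206925 to 207532) in neuron-like, 264682 CPM (263107 to 266265) in astrocyte-like and 112781 CPM (111535 to 114037) in oligodendrocyte-like cells, against 43884 CPM (43548 to 44223) in microglia-like cells. Malat1 (ENSMUSG00000092341, chromosome 19, 5795690 to 5802672) alone reached 258458 CPM in astrocyte-like, 154675 CPM in neuron-like and 41335 CPM in microglia-like cells. Meg3, an imprinted neuronal transcript (ENSMUSG00000021268, chromosome 12, 109541001 to 109571726), stood at 35733 CPM (35607 to 35859) in neuron-like and 1652 CPM in microglia-like cells, and Snhg11 at 14729.5 and 589 CPM. In library 2 the group took 34305 CPM (34190 to 34421) in microglia-like, 38542 CPM in endothelial-like, 68713 CPM in oligodendrocyte-like and 83644 CPM in pericyte-like cells. The microglia-like median over the other classes was -3.09 (-3.14 to -3.03, 5 of 5 lower, percentile 1.23) in library 1 and 0.03 (-0.18 to 0.11, percentile 57.6) in library 2, where 5 alternative settings gave values from -1.77 to -0.00205. The lowest 2, -1.77 and -1.40, came with neuron-like cells in the comparison, and against the same 3 classes they were -0.0448 and -0.0134. In library 1 the median was -1.65 with no doublets removed, and -1.58 against the same 3 classes, so the classes compared did not make this change.

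Mitochondrially encoded genes were lowest in neuron-like cells among the 4 classes compared in library 1. These had 13352 CPM (13275 to 13429), microglia-like cells 23343 CPM (23098 to 23590), astrocyte-like cells 31234.5 CPM and oligodendrocyte-like cells 52487 CPM, with mt-Co3 leading in microglia-like cells at 4639 CPM. Ribosomal protein mRNAs took 5964 CPM (5913 to 6016) of neuron-like, 9214 CPM of astrocyte-like, 26946 CPM of oligodendrocyte-like and 62001 CPM (61601 to 62403) of microglia-like cells. In library 2 the mitochondrial genes stood at 42017 CPM (41889 to 42145) in microglia-like, 56818 CPM in endothelial-like, 58814 CPM in pericyte-like and 69991 CPM in oligodendrocyte-like cells, and ribosomal protein mRNAs took 87690 CPM of microglia-like and 123306 CPM of endothelial-like cells. The microglia-like medians for mitochondrial genes were -0.43 (percentile 21.4) and -0.53 (percentile 9.63). The first turned to 0.92 with at least 2000 UMIs, where 35 oligodendrocyte-like and 21 astrocyte-like cells remained, so both classes left the comparison and only neuron-like cells stayed in it, and was -0.64 against the same 3 classes.

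Myelin genes separated oligodendrocyte-like cells from all other classes compared, with 43890.1 CPM (43114 to 44676) in library 1 and 58379.8 CPM (57711 to 59055) in library 2. Mbp, a structural protein gene of compact myelin, stood at 6627 and 5405 CPM, Cnp at 4613 and 4605 CPM, and Mag, an adhesion molecule gene of the myelin sheath, at 4541 and 2836 CPM. Myelin genes were also counted in every other class, at 795 CPM (750.3 to 842) in microglia-like, 688 CPM (671 to 706) in neuron-like and 1092 CPM (993 to 1198) in astrocyte-like cells of library 1, and at 143 CPM (136 to 151) in microglia-like and 52.7 CPM (44.9 to 61.5) in endothelial-like cells of library 2. The microglia-like medians were -4.21 (-4.36 to -3.99, percentile 0.015) and -7.79 (-8.11 to -7.44, percentile 0.0), with 7 of 7 genes lower in each. They turned to 0.40 and 1.26 with at least 2000 UMIs and to 0.78 in library 2 clustered on its own, where 35, 32 and 33 oligodendrocyte-like cells were left and the class dropped out, in library 1 together with the astrocyte-like cells. Against the same 3 classes they were -4.53, -7.85 and -7.93.

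The share of cells with at least 1 UMI was compared after every cell had been thinned to 1000 UMIs. P2ry12 was then counted in 94.0% (91.9 to 95.7%) of the 663 microglia-like cells of library 1 and 92.1% (90.5 to 93.4%) of the 1448 of library 2, against 1.17% (0.880 to 1.52%) of neuron-like cells and 3.14% (1.16 to 6.71%) of endothelial-like cells, which should lack it. Before thinning, the median depth was 2195 and 6529 UMIs in the microglia-like cells, 1661 in the neuron-like cells of library 1 and 8011 in the endothelial-like cells of library 2. Jun was counted in 53.4% (50.8 to 56.0%) of microglia-like and 58.1% (50.8 to 65.2%) of endothelial-like cells of library 2, against 22.0% (11.5 to 36.0%) of oligodendrocyte-like and 6.02% (1.98 to 13.5%) of pericyte-like cells. In library 1 it was counted in 12.5% (10.1 to 15.3%) of microglia-like, 15.6% (9.36 to 23.8%) of oligodendrocyte-like, 8.36% (7.58 to 9.19%) of neuron-like and 6.31% (3.84 to 9.68%) of astrocyte-like cells. Fos, the partner of Jun in AP-1, was found in 27.8% (25.5 to 30.2%) of microglia-like and 33.0% (26.4 to 40.1%) of endothelial-like cells of library 2. In library 1 it was found in 0.452% (0.0934 to 1.32%) of microglia-like, 1.52% (1.18 to 1.91%) of neuron-like, 0.917% (0.0232 to 5.01%) of oligodendrocyte-like and 0.664% (0.0806 to 2.38%) of astrocyte-like cells. By summed UMIs Fos stood at 2.69 CPM (0.734 to 6.89) in microglia-like and 19.43 CPM (16.6 to 22.6) in neuron-like cells of library 1. Egr1, an early zinc finger factor, was in 30.6% (28.2 to 33.0%) of microglia-like cells of library 2 and 0.905% (0.333 to 1.96%) of those of library 1, where neuron-like cells had 4.22% (3.66 to 4.84%).

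Ccl4 was counted in 22.9% (20.7 to 25.1%) of thinned microglia-like cells of library 2, against 1.57% (0.325 to 4.52%) of endothelial-like cells, and Ccl3 in 18.0% (16.1 to 20.1%) against 1.05% (0.127 to 3.73%). In library 1 Ccl3 was in 2.11% (1.16 to 3.52%) of microglia-like cells and in 0.0433% (0.00525 to 0.156%) of neuron-like cells, and in 0 of 109 oligodendrocyte-like cells (upper bound 3.33%). Ccl4 was in 1.06% (0.426 to 2.16%) of microglia-like cells of library 1. Hspa8 was counted in 57.0% and 68.9% of microglia-like cells, in 79.1% of endothelial-like and 15.6% of neuron-like cells.

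Markers of other cell types were summed in the microglia-like cells beside their own, which took 57013.5 CPM and 54141 CPM. Neuron markers stood at 460.5 CPM in library 1 and 56.6 CPM in library 2, oligodendrocyte markers at 921 and 147 CPM, and astrocyte markers at 491 and 289 CPM. Choroid plexus markers stood at 205 and 1764 CPM, erythrocyte markers at 30.3 and 318 CPM, B cell markers at 327 and 267 CPM, neutrophil markers at 176 and 258 CPM, and markers of monocytes or dendritic cells at 141 and 171 CPM. The other 9 lists (T or NK cell, border-associated macrophage, endothelial, ependymal, fibroblast, neuroblast or progenitor, oligodendrocyte precursor, pericyte or smooth muscle, and proliferating cells) each lay between 3.54 and 81.5 CPM in both libraries.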

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

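The sums in barcodes and cells that the main comparisons do not use were chosen only after the data had been seen. They are listed because their level exceeds what a count of 0 allows, a bar that any abundant gene group passes.

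The 6317 barcodes of library 1 that the filters left out held 842.9 CPM of immediate early genes (821.8 to 864.3) and were used only in some of the alternative settings. The 4373 barcodes left out of library 2 held 3692 CPM (3660 to 3725). The same barcodes held homeostatic microglia genes at 2613 CPM in library 1 and 5596 CPM in library 2. A mixed immune cluster that stayed unnamed, with 11 cells of library 1 and 67 of library 2, held 35799.8 CPM of antigen presentation genes (35376 to 36228). The class II genes Cd74 and H2-Eb1 were among the leading genes in 3 of its 5 parts, and the macrophage markers Mrc1 and Pf4 in 2 of them.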

How the results depend on the processing

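The settings for 68 of the results below were applied only after the data had been seen, and those for the other 10 were planned. No paired analysis and no analysis without single replicates was possible, because each library is 1 pool with no group. Of 92 planned values, 65 stayed within the counting interval of the reported value, 26 left it and 1 changed sign. Of the 746 added values of the other results 16 changed sign, and 0 of 8 added for the 10. Added too were the medians against the same 3 classes as reported, where a setting moved classes across the limit of 50 cells.

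With at least 500 UMIs and 250 genes the microglia-like share was 8.60% in library 1 and 64.1% in library 2, the immediate early level of library 1 was 2394 CPM and its median ratio reversed to -0.12. With at least 2000 UMIs the share of library 1 was 19.7%, the immediate early level of library 2 was 21585 CPM and the medians were 0.83 and 1.30. With a mitochondrial limit of 20% library 2 had a share of 60.7%, 20875 CPM of immediate early and 4376 CPM of heat shock genes, and a median of 2.04. With no doublets removed, library 1 had 2407 CPM of immediate early and 2374 CPM of heat shock genes, and library 2 had 20947 CPM of immediate early and 3409 CPM of NF-kB genes and a median of 1.05. With response genes in the clustering the values of library 2 were 21404 CPM and 1.08. Clustered on its own, library 2 had a share of 67.7%, 20945 CPM of immediate early and 3417 CPM of NF-kB genes, and a median of 0.59. Over nuclear-encoded UMIs only, its levels were 22105 CPM (immediate early), 4612 CPM (heat shock) and 3605 CPM (NF-kB). Its median was 1.35 over genes with at least 20 UMIs.

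In 5 settings the classes with at least 50 cells changed. With at least 2000 UMIs library 1 kept neuron-like cells only, and in library 2 oligodendrocyte-like cells (32) left and erythrocyte-like cells (50) joined. Oligodendrocyte-like cells (33) also left in library 2 on its own. Neuron-like cells of library 2 joined with at least 500 UMIs (195) and with a mitochondrial limit of 20% (58), with 3 further classes in the latter. In library 1, 4 classes joined with at least 500 UMIs, choroid plexus-like cells with 20% mitochondrial UMIs and fibroblast-like cells with no doublets removed. Against the same 3 classes the immediate early medians were 0.67 (library 1) and 1.07 (library 2) with at least 500 UMIs, 0.46 and 1.12 with at least 2000 UMIs, 0.45 and 1.23 with 20% mitochondrial UMIs, 0.63 (library 1) with no doublets removed and 1.03 (library 2) on its own.

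Other medians that changed sign were those of myelin genes (0.40 in library 1 and 1.26 in library 2 with at least 2000 UMIs, 0.78 in library 2 on its own), mitochondrial genes (0.92 in library 1 with at least 2000 UMIs) and, in library 2, antigen presentation genes (-0.0341 with at least 2000 UMIs, -0.89 with 20% mitochondrial, -0.47 on its own). Against the same 3 classes none of these changed sign, so the classes compared made these changes. Nuclear-retained RNAs of library 2, at 0.03, turned to -1.77 (at least 500 UMIs), -0.33 (at least 2000), -1.40 (20% mitochondrial), -0.0345 (no doublets removed) and -0.00205 (nuclear-encoded UMIs). Against the same 3 classes the first 3 were -0.0448, -0.27 and -0.0134. Hypoxia and glycolysis genes of library 1 turned to -0.44 only against the same 3 classes with at least 2000 UMIs, where 21 astrocyte-like cells were left. For the other changes the cause was not tested. Depth limits library 1 most, where a count of 0 of Tnf in oligodendrocyte-like cells allows up to 10.8 CPM.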

Other observations

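The tests of free RNA from other cells, of a shift of all genes, of free neuronal RNA and of doublets with another class were chosen only after the result was seen, and so was the contrast of clusters within library 2.

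Microglia-like cells of library 2 fell into 2 large clusters that differed in immediate early genes although these genes had been kept out of the clustering. The first held 704 cells (48.6% of the library's microglia-like cells) with 34291 CPM of immediate early genes, and the second 645 cells (44.5%) with 5009 CPM, a ratio of 6.85 (6.75 to 6.94). Of the 27 genes, 24 were at least 2 times higher in the first cluster, among them Fos (2747 against 122 CPM), Egr1 (1789 against 133 CPM), Atf3 (1085 against 48.9 CPM) and Jun (5773 against 720.02 CPM). Fos was counted in 70.2% of its cells and in 11.9% of the others. NF-kB and cytokine genes followed (5571 against 835 CPM, 6.67 times), and heat shock genes less so (1.52 times). Mitochondrial genes were higher for 13 of 13 genes (1.13 times), interferon response genes for 10 of 12 (1.17 times), antigen presentation genes for 8 of 9 (1.15 times) and disease-associated genes for 11 of 16 (1.04 times). Homeostatic microglia genes went slightly the other way (0.888 times, 0 of 12 higher), and unfolded protein response genes (0.978 times) and hypoxia and glycolysis genes (1.01 times) were near 1. A further 36 microglia-like cells of library 2 sat in a small cluster with 1 of library 1 that was led by the mast cell genes Cma1 and Cpa3.

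The microglia-like cells of the unassigned libraries are given here as values, with no method attached. Immediate early genes stood at 2508 CPM in library 1 and 21176 CPM in library 2, a ratio of 8.44 (8.18 to 8.73, 23 of 27 genes higher). These are different clusters: of the 663 cells of library 1, 642 lay in a cluster with 2431 CPM that held 7 cells of library 2. The first large cluster of library 2 stood at 14.1 times that level (13.6 to 14.6) and the second at 2.06 times (1.99 to 2.14). NF-kB and cytokine genes had a ratio of 5.79 (5.42 to 6.20), heat shock genes 1.73 (1.68 to 1.79), mitochondrial genes 1.80 and antigen presentation genes 1.66. Hypoxia and glycolysis genes had a ratio of 1.48, but 6 of 12 were higher and 6 lower (median log2 ratio 0.01), and Hk2 (120.5 and 478 CPM) made up most of the difference. Homeostatic microglia genes (0.972), disease-associated genes (0.940), unfolded protein response genes (1.05), interferon response genes (1.10) and reactive astrocyte genes (0.770, 0.490 to 1.26) were closer to 1. Nuclear-retained RNAs (0.782) and myelin genes (0.180) were lower in library 2. The 12 genes with the highest ratio were Fos, Dusp1, Egr1, Hspa1b, Fosb, Hspa1a, Zfp36, Hist1h1d, Socs3, Atf3, Jun and Ier2. Of these Fos had 4 UMIs in library 1 and 15610 in library 2 (ratio 586, 229 to 2151), and Jun 211 and 34719 (24.7, 21.6 to 28.4). The median over all 8817 genes compared was -0.15 (log2). In oligodendrocyte-like cells, with 109 and 50 cells, the ratios were 1.63 (1.45 to 1.84) for immediate early and 1.62 (1.52 to 1.72) for heat shock genes. Nuclear-retained RNAs differed there as well (0.609, 5 of 5 lower), as did mitochondrial genes (1.33, 13 of 13 higher), and 73 of the 109 but 17 of the 50 cells lay in 1 of the 2 oligodendrocyte-like clusters. Over the alternatives the level of library 1 ran from 772 to 1783 CPM for immediate early and from 2595 to 6168 CPM for heat shock genes, so these 2 ratios depend on the settings.

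The 12 genes with the lowest ratio in microglia-like cells were Ly6h, Cck, Nell2, Caly, Meg3, Snhg11, Rian, Pcsk1n, Gpm6a, Thy1, Slc24a2 and Aplp1. Each had a higher level in neuron-like cells of library 1 than in the microglia-like cells of that library, from 235 CPM (Thy1) to 35733 CPM (Meg3). Meg3 stood at 1652 CPM in microglia-like cells of library 1 and 67.0 CPM in those of library 2.

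For the immediate early ratio between the libraries, depth may carry a part: 46 microglia-like cells of library 2 with 1830.5 to 2585.5 UMIs, the quartiles of library 1, stood at 5834 CPM, or 2.33 times library 1 (2.13 to 2.54), down from 8.44. This exceeds the bound of 2 set in advance for depth alone, but 33 of the 46 cells lay in 3 small clusters (2934 CPM together), 5 in the first large one (30326 CPM) and 6 in the second (1074 CPM, 601 to 1772, below library 1), so depth and cluster were not separated. The small clusters with 37 and 36 cells of library 2 held only 1556 and 4107 CPM of nuclear-retained RNAs. The large ones held 34276 and 35569 CPM, so these small clusters differed in more than depth. Free RNA spread over all cells of library 2 would raise every class, but pericyte-like cells reached only 0.0857 of the microglia-like level. A shift of all genes of like expression would leave the group among random lists, and it lay at percentile 100. What set the libraries apart stays open, and no biological explanation was tested, since the labels give no group.

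Neuron-like cells of library 1 had few mitochondrial and many nuclear-retained RNAs, and the mitochondrial limit did not make this, as a limit of 20% changed their median share only 1.06 times. Free neuronal RNA does not account for it, with Meg3 in microglia-like cells at 0.0462 of the neuron-like level. Loss of cytoplasmic RNA is a candidate explanation: ribosomal protein mRNAs stood at 0.243 (0.233 to 0.254) of the level in neuron-like cells of library 2. That level rests on 37 cells with 6168 CPM of choroid plexus markers, 20 of them in a cluster with 0 cells of library 1, and the class ran from 0 cells (library 2 on its own) and 17 (Leiden resolution 0.5) to 58 (20% mitochondrial) and 195 (at least 500 UMIs). Unlike clusters are thus compared, so this explanation stays open, and no biological one was tested. High nuclear-retained RNAs were not particular to neuron-like cells of library 1. Astrocyte-like cells held 264682 CPM and fibroblast-like cells 209298 CPM, but microglia-like cells 43884 CPM and choroid plexus-like cells 32509 CPM. Ribosomal protein mRNAs stood at 9214 CPM in astrocyte-like cells of library 1 and 24219 CPM in the 23 of library 2. In fibroblast-like cells (40 and 36) they stood at 10959 and 61538.5 CPM.

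For the 2 clusters of library 2, the ratio stayed at 4.74 or more within 4 quartiles of UMIs per cell and at 5.09 or more within 4 quartiles of the mitochondrial share, so neither accounts for it. Doublets with another class are unlikely to be the source, because the highest other class, endothelial-like cells, reached only 0.541 of the first cluster's level. That class level is a sum over 3 clusters of unlike depth, which were not taken apart. What else set the 2 clusters of this single pool apart stays open, and no biological explanation was tested.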
